A study of Mus musculus with 6 samples.

How the data were processed

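RNA was measured in 6 libraries of neuron-enriched cells from male mice on day 4 after a 60-minute middle cerebral artery occlusion, 3 labelled control and 3 labelled cKO. Per the labels' protocols, peri-infarct cortex was trimmed, treated with pronase for 75 minutes, dissociated and sorted for Thy1-positive cells lacking ACSA2, CD31, CD45 and O4, which mark astrocytes, endothelium, leukocytes and oligodendrocytes. RNA was purified with a column kit and libraries were made with the Ovation SoLo RNA-Seq kit, per the labels' protocols. The submitters' processing notes name Trimmomatic, HISAT2, featureCounts and edgeR, with no versions, and the mm10 build. The strand setting, the annotation used for counting and the treatment of reads with several matches are not given in the sources used here, so genes that overlap an antisense gene or have close paralogs carry that uncertainty.

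The deposited table holds 24419 gene symbols and 1 column per library. The values were handled as a normalized signal, deposited as depth-scaled read counts (CPM) rescaled again per library, since the column totals ran from 961962 to 1027958 rather than being equal. In each library the values were whole multiples of 1 step, so whole reads were recovered, with 100% of values within 0.001 of a whole number. The scaling factors, from 0.962 to 1.028, were those implied by the column totals. The design had assumed plain CPM, and the main test was kept because it fits either form. Recovered depth ran from 10094145 to 24056755 reads per library, and 3 reads were taken as the detection floor, 0.126 to 0.303 deposited units.

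The main test was limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2(value + 1), for genes with a value of at least 1 in at least 3 libraries, which left 14796 genes. Fold changes are on that scale, which understates the change of low genes, and are given as labelled cKO minus labelled control with the standard error (SE). P-values were adjusted with the Benjamini-Hochberg method and called at an adjusted p under 0.05. Gene lists with at least 5 tested members were compared with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry. For Padi4 an exact two-sided permutation test of log2(value + 1) and exact Poisson 95% intervals were used. Intervals and floors treat reads as independent and cover counting error only. Reads may be copies of fewer molecules, so the intervals may be too narrow. The labels do not say that libraries came from separate animals, so p-values measure the spread between these samples, which may be technical.

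The lists, the design and the rule for named genes were set before the data were examined. That rule takes the Padi genes, the sort and Cre driver genes, and 12 genes per direction past the adjusted threshold with a mean of at least 2 and no overlap between groups. Where fewer pass, it fills up by smallest unadjusted p. It adds up to 4 members of each described list by smallest unadjusted p. Predicted genes without a symbol were skipped, 28 in the higher and 20 in the lower direction. The script had first skipped some clone-type and antisense symbols too, and was narrowed to the rule after a first run had been seen, which put AA388235 in place of Mroh7. Outside the rule, Snap25, C1qb, S100a8, S100a9, Csf3r, Apoe, P2ry12, Cx3cr1, Fn1, Col1a1, Col3a1, Spp1, Cspg4, Xist, Ddx3y and the genes called by another split were chosen after their values were seen.

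The 42 lists covered neuronal, glial, vascular, ependymal and blood cell markers, synapse, ion channel, axon and neurogenesis genes, immediate early and regeneration genes, growth factors, cytokines, interferon, MHC and complement genes, and stress, metabolic, ribosomal, chromatin and cell cycle genes. Of these, 37 were tested and 5 were not. The neutrophil list had 2 tested members, the T and B lymphocyte list 2, the red cell list 1 and the peptidylarginine deiminase list 1, and 0 symbols matched the mitochondrially encoded list.

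Alternatives were pseudocounts of 0.1 and 5, no filter, a filter at 5, median-of-ratios factors, quantile normalization, array weights, robust eBayes, a replicate block, leaving out each library, and edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads. Leaving out both libraries numbered 2 was chosen after the data were seen.

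The procedure was tested on simulated data for this comparison, with 200 genes changed before the filter and 14157 genes run after it. Counts were drawn independently for each gene and library, with the trended spread of the real libraries. Differences that many genes share between real libraries were left out, so recovery in the real data may differ. Limma recovered 0 of 47 genes changed 2-fold, 15 of 46 changed 4-fold, 32 of 46 changed 8-fold and 34 of 45 changed 16-fold, and called 12 of 13973 unchanged genes. In a second simulation, over 14796 genes drawn independently, a list of 34 members was shifted by a log2 of -1. It had an adjusted p of 4.94e-20 with camera's preset correlation and 0.0142 with an estimated one. Of 36 other lists, 0 were called. Because the genes were independent, this could not test the preset correlation on lists whose members vary together. In the real libraries the estimated correlation ran from -0.0194 for phospholipase A2 and eicosanoid genes to 0.816 for ribosomal protein genes.

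Gene positions come from GENCODE release M21 on the same build as the submitters' notes name. Of the table's symbols, 23309 matched 1 gene, 41 matched several and 1069 had no match. Figures were drawn with matplotlib 3.10.9.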

Results

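Neuron-enriched cells were profiled by RNA sequencing in mouse cortex bordering an infarct, on day 4 after a 60-minute occlusion of the middle cerebral artery. The 3 libraries labelled control came from mice with loxP-flanked Padi4 alleles alone. The 3 libraries labelled cKO came from mice that also carried Cre drivers at Slc17a7 and Slc32a1, the vesicular transporter genes of glutamatergic and GABAergic neurons. The comparison asked which transcripts differ when Padi4 is deleted in neurons after stroke. Control replicates 1 to 3 held 10638387, 13077507 and 18502027 reads, and cKO replicates 1 to 3 held 20819131, 10094145 and 24056755. Replicate 2 had the fewest detected genes of each group, 15261 in the library labelled control and 14042 in the library labelled cKO, against 16818 to 17891 in the other 4. Values below are deposited scaled CPM, given as mean ± SD over the 3 libraries of a group.

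Padi4, the targeted gene, encodes peptidylarginine deiminase 4, an enzyme that converts arginine to citrulline in histones and other proteins. It did not bear out the labels. In the libraries labelled control, 0 reads were assigned to Padi4 in each of the 3, below floors of 0.277, 0.221 and 0.167. In the libraries labelled cKO, 0, 3 and 12 reads were assigned in replicates 1, 2 and 3, at 0, 0.303 and 0.505. Pooled over each group, this was 15 of 54970031 reads, or 0.273 CPM with an exact Poisson 95% interval of 0.153 to 0.450, against 0 of 42217921 reads, with an interval of 0 to 0.0874 CPM. Of the 15 reads, 12 were in 1 library, replicate 3. The log2 difference was 0.32, with an exact permutation p of 0.4 where the smallest possible is 0.1. Which exons are flanked by loxP sites is not given in the sources used here, so reads outside a deleted part cannot be separated from intact transcript. The gene lies on chromosome 4 from 140745865 to 140774236 on the minus strand in mm10. Group names in what follows are the labels, and every direction is that of the labels, which Padi4 did not bear out.

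Among the other deiminase genes, Padi1 and Padi3 had 0 reads in all 6 libraries and Padi6 had group means of 0.160 and 0.416. Padi2 was measured at 38.2 ± 9.46 in the libraries labelled control and 41.1 ± 32.2 in those labelled cKO (SD, n = 3 each). The sort and Cre driver genes showed no difference past the threshold, Ptprc being too low to be tested. Thy1, the positive sort marker, was at 125 ± 34.1 and 212 ± 151, and Slc17a7 at 140 ± 59.3 and 203 ± 232. Slc32a1 was at 7.87 ± 4.41 and 19.2 ± 18.6. Of the genes tied to excluded surface markers, Atp1b2, which encodes the ACSA2 antigen, was at 195 ± 56.8 and 309 ± 90.6. Pecam1, which encodes CD31, was at 5.53 ± 1.22 and 3.70 ± 3.43, and Ptprc, which encodes CD45, at 0.676 ± 0.510 and 0.784 ± 1.36.

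Transcripts of several cell types were present in every library. Summed over 24 oligodendrocyte markers, levels ran from 15780 to 46880, above the pan-neuronal sums of 3318 to 13040 in each library. The neuronal gene Snap25 was at 1334 ± 753 over the 6 libraries (SD). Pericyte, smooth muscle and fibroblast markers summed to 5684 to 8880 in control replicate 1, cKO replicate 1 and cKO replicate 3, and to 851 to 1417 in the other 3. Among microglial and neutrophil genes, C1qb reached at most 10.8 and S100a8 at most 1.67 in any library.

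**Figure D1:**
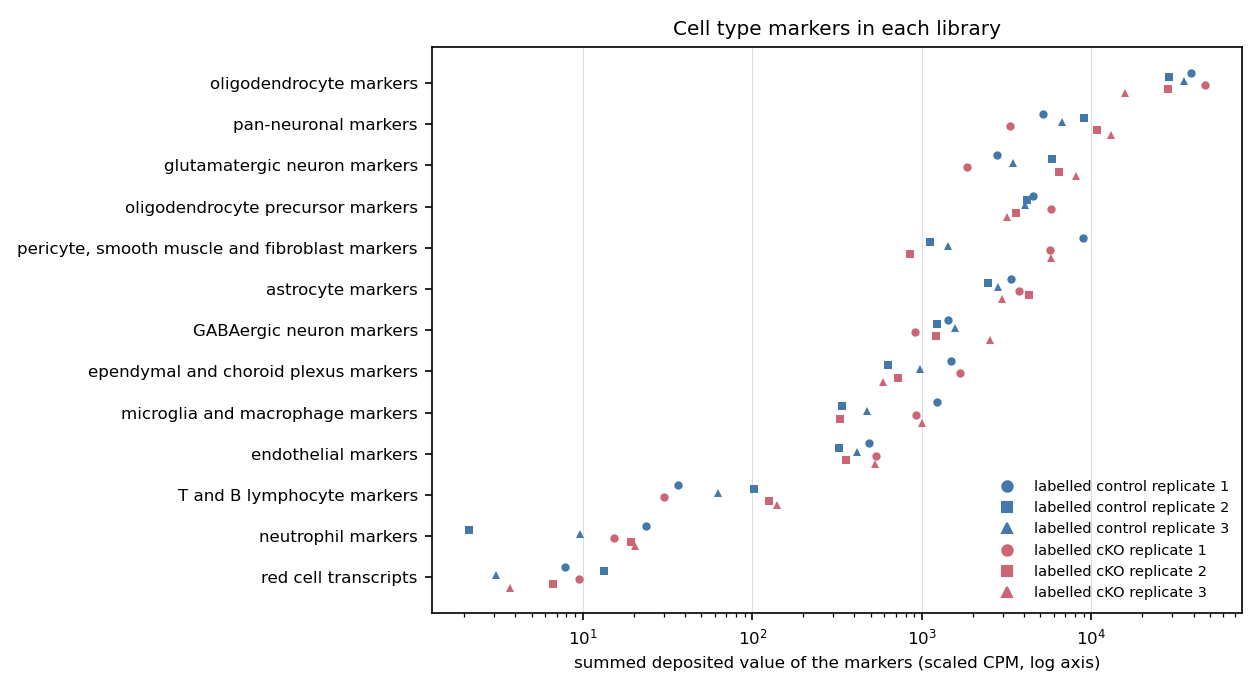
Summed deposited values of each marker list (scaled CPM, log axis), one point per library, with blue for labelled control, red for labelled cKO and the symbol for the replicate number. Oligodendrocyte markers ran from 15780 to 46880 and lay above the pan-neuronal sums of 3318 to 13040. Some sums rest largely on 1 gene and need not reflect the named cells. Bcl11a had a mean of 77.3 in the lymphocyte list, where the next gene, Lck, had 2.23. Enpp2 had a mean of 984 in the ependymal and choroid plexus list, where the next gene, Foxj1, had 11.7.

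In the comparison of the groups, no single gene passed the adjusted threshold in limma, and interferon-stimulated genes were the group that stood lowest in the libraries labelled cKO. These genes are switched on by type I interferon and act in antiviral defence. Of 34 tested members, 30 were lower and 4 higher in the libraries labelled cKO, with a median log2 fold change of -0.97. The list fell in the camera test at the preset correlation of 0.01 (adjusted p = 2.06e-15). Its estimated correlation was 0.198, and camera with that estimate gave an adjusted p = 0.90. In 13 of the 34 members every library labelled cKO lay below every library labelled control, and in 0 above, where chance gives no overlap in 10% of genes over both directions.

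Ifit3, an interferon-induced tetratricopeptide repeat gene, had a mean of 35.9 ± 10.1 in the libraries labelled control and 6.48 ± 1.48 in those labelled cKO, a log2 fold change of -2.29 (SE 0.48). Ifit1, of the same family, was at 33.5 ± 4.20 and 9.89 ± 1.64 (log2 fold change -1.67, SE 0.43). Usp18, which restrains interferon receptor signalling, was at 13.2 ± 5.54 and 2.42 ± 3.35, and Ddx58, which encodes the RNA sensor RIG-I, at 40.1 ± 5.56 and 12.7 ± 11.6. Ifit3b had a log2 fold change of -2.32. None passed the adjusted threshold over all genes in limma, while 1 list member, Ifit3, passed when adjusted over the list alone. Ifit3 lies on chromosome 19 from 34583531 to 34588731 on the plus strand in mm10, near its close paralog Ifit3b at 34607970 to 34613401, and reads could be split between them. Mean log2 levels over the list were 4.01, 3.60 and 3.89 in control replicates 1 to 3 and 3.40, 2.27 and 2.86 in cKO replicates 1 to 3. An exact permutation test of these means gave p = 0.1, the smallest that 3 against 3 allows. Chromatin regulator genes, not called by camera (adjusted p = 0.425), also reached p = 0.1 in the permutation test. With the preset correlation the interferon call held without each library in turn, with mean log2 fold changes from -1.27 to -0.71. It was lost with fry, at adjusted p of 0.987 for the directional and 0.335 for the mixed test. Oligodendrocyte markers were also lower on average in the libraries labelled cKO, though their highest mean log2 level was in cKO replicate 1 (9.46). The lowest mean of the interferon list was in cKO replicate 2, the library with the fewest detected genes.

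**Figure D2:**
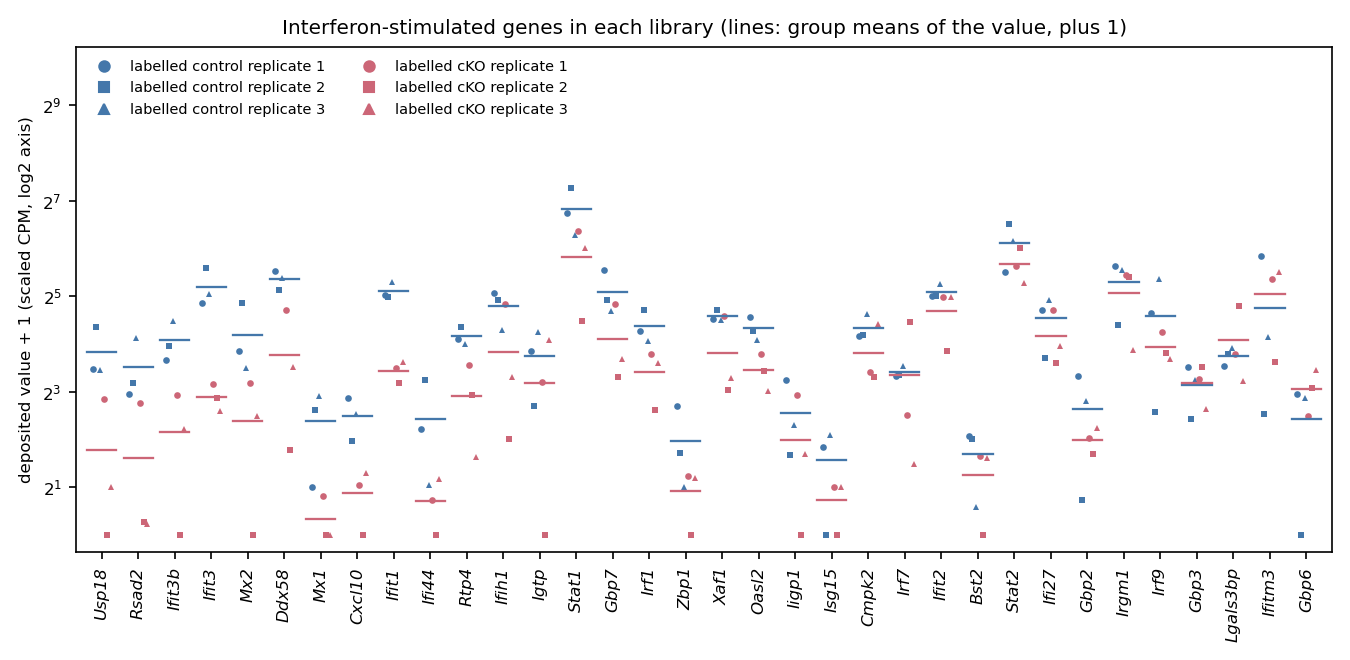
Deposited value plus 1 (scaled CPM, log2 axis) of the 34 tested interferon-stimulated genes, one point per library and a line for each group mean, in order of log2 fold change. Of these genes, 30 were lower in the libraries labelled cKO, and 13 showed no overlap between the groups.

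Outside that list, the lower genes with the smallest unadjusted p included Cd44, Dlk1, Rep15, Nupr1, Chdh, Irgm2 and Ddx60, none past the adjusted threshold. The last 2 had log2 fold changes of -2.26 and -2.73. The list was fixed beforehand, so a gene outside it may still respond to interferon. The annotation places Igtp, a member of that list, over Irgm2 on the same strand, so their reads may not be separate. Cd44, a hyaluronan receptor, was at 224 ± 113 in the libraries labelled control and 84.3 ± 33.9 in those labelled cKO (log2 fold change -1.36, SE 0.41). Nupr1, a stress-induced nuclear protein gene, was at 19.1 ± 9.16 and 3.68 ± 3.07, and Chdh, encoding choline dehydrogenase, at 46.7 ± 8.97 and 20.1 ± 9.25. On the higher side the first gene was Ddn, which encodes the dendritic protein dendrin, at 43.8 ± 5.56 and 126 ± 63.6 (log2 fold change 1.35, SE 0.43). The annotation places an antisense gene over Ddn, and the strand setting is not given in the sources used here. Col20a1 was at 52.8 ± 13.2 and 117 ± 54.8, and Sfrp1, encoding a secreted Wnt antagonist, at 7.83 ± 2.25 and 26.6 ± 17.8. The other 9 higher genes named by the rule were Rnaset2b, Ankrd29, Sebox, Endou, Scand1, Rhbdl3, Ccdc89, AA388235 and Krt9, with group means of at most 12.9.

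Stress-related and translation-related lists fell with camera's preset correlation, and all had an adjusted p = 0.972 with an estimated correlation. Of 42 integrated stress and unfolded protein response genes, 39 were lower (adjusted p = 0.00138). Psat1 and Phgdh, which encode enzymes of serine synthesis, were at 249 ± 7.76 and 165 ± 84.1 and at 45.3 ± 2.51 and 27.5 ± 15.5 in the libraries labelled control and cKO. Heat shock genes were lower in 19 of 25 (adjusted p = 0.0469), with the chaperone gene Hsph1 at 243 ± 43.2 and 164 ± 52.1. Immediate early genes, induced by activity, were lower in 29 of 34 (adjusted p = 0.0469), with Nr4a2 at 54.3 ± 19.2 and 24.7 ± 18.1. Ribosomal protein genes were lower in 60 of 76 (adjusted p = 0.0159), with Rpl23 at 75.5 ± 18.1 and 51.6 ± 17.2. The library means of these 4 lists did not part by label. An exact permutation test of the means gave p = 0.5 for the stress response list and for heat shock genes. It gave 0.3 for immediate early genes and 0.6 for ribosomal protein genes. Leaving out control replicate 1, control replicate 3 or cKO replicate 2 ended each of these 4 calls as a fall. Without control replicate 1, control replicate 3 and cKO replicate 2 in turn, the mean log2 fold change was -0.23, -0.19 and -0.06 for the stress response list, -0.10, -0.05 and -0.02 for heat shock genes, -0.27, -0.17 and -0.11 for immediate early genes, and -0.10, -0.01 and 0.22 for ribosomal protein genes, which were then called higher without cKO replicate 2. The immediate early call also ended without cKO replicate 3, at -0.19, and the heat shock call without cKO replicate 1, at -0.28. A pseudocount of 0.1 or no filter also ended the immediate early call, at -0.27 and -0.24, and the heat shock call, at -0.20 and -0.21, and edgeR on recovered reads ended the immediate early call, at -0.18.

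Marker lists of some cell types also passed the camera threshold at the preset correlation, and their library means did not part by label either. An exact permutation test of these means gave p = 0.3 for astrocyte and for ependymal and choroid plexus markers. It gave 0.4 for oligodendrocyte markers, 0.7 for pan-neuronal markers and 0.8 for postsynaptic genes, where the smallest possible is 0.1. The library labelled cKO replicate 1 had the lowest pan-neuronal mean log2 level (6.11) and the highest oligodendrocyte one (9.46). Astrocyte markers rose, with 21 of 25 higher and a median log2 fold change of 0.53 (camera adjusted p = 0.000266), and adjusted p = 0.972 with an estimated correlation. Slc4a4, a bicarbonate transporter gene, was at 39.3 ± 8.60 and 69.8 ± 45.2, and Mlc1 at 2.10 ± 2.19 and 12.2 ± 12.5. Pan-neuronal markers were higher in 18 of 24 and postsynaptic genes in 32 of 45, both with camera adjusted p = 0.0414 and adjusted p = 0.972 with an estimated correlation. Tubb3, a neuronal tubulin gene, was at 77.3 ± 13.9 and 124 ± 29.6, and Gria1, a glutamate receptor subunit gene, at 98.6 ± 21.6 and 209 ± 139. Ependymal and choroid plexus markers were higher in 5 of 7 (adjusted p = 0.0469, and adjusted p = 0.972 with an estimated correlation), with the cilia regulator Foxj1 at 6.62 ± 4.57 and 16.8 ± 8.12. Oligodendrocyte markers were lower in 21 of 24, with a median of -0.30 (adjusted p = 0.00674, and adjusted p = 0.972 with an estimated correlation). Gjb1, a gap junction gene, was at 154 ± 70.7 and 68.4 ± 70.4, and Opalin, a myelin gene, at 140 ± 53.5 and 80.8 ± 69.8.

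Single libraries decided these marker calls. The astrocyte call ended without cKO replicate 2 (mean log2 fold change 0.18). The oligodendrocyte call ended without control replicate 1 (-0.32) or cKO replicate 3 (-0.07), the latter with the sign of the test reversed. The pan-neuronal call ended without control replicate 1 (0.05), control replicate 3 (0.19), cKO replicate 2 (0.04) or cKO replicate 3 (-0.20), and under quantile normalization (0.22). The postsynaptic call ended without control replicate 1 (-0.03), control replicate 3 (0.18), cKO replicate 2 (-0.02) or cKO replicate 3 (-0.09), and under quantile normalization (0.15). The ependymal call ended without control replicate 2 (0.41), control replicate 3 (0.56), cKO replicate 1 (0.67) or cKO replicate 2 (0.67). It also ended under quantile normalization (0.65), array weights (0.59), a replicate block (0.69), a pseudocount of 0.1 (1.18) and DESeq2 (0.98). With no filter the pan-neuronal (0.22), postsynaptic (0.17) and ependymal (0.42) calls ended. Without both libraries numbered 2, a setting chosen after the data were seen, the pan-neuronal (0.24), ependymal (0.32) and immediate early (-0.15) calls ended.

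**Figure D3:**
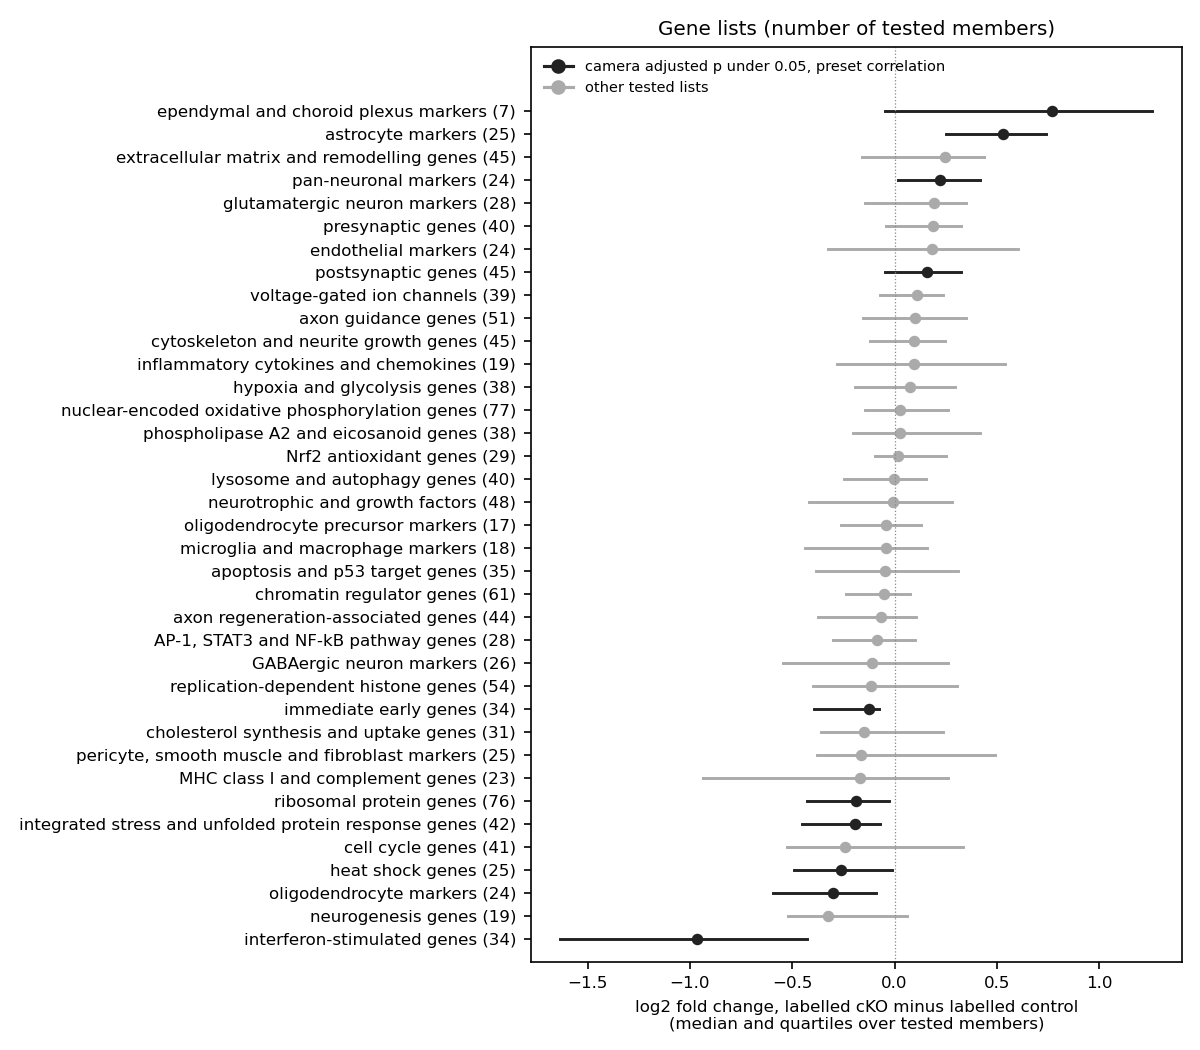
Median log2 fold change of each tested list, labelled cKO minus labelled control, with bars for the quartiles over its tested members and black for the 10 lists past the camera threshold at the preset correlation. Interferon-stimulated genes lay lowest, with a median of -0.97.

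The other 27 tested lists did not pass the camera threshold. Among neuronal groups, 17 of 28 glutamatergic markers, 12 of 26 GABAergic markers, 27 of 40 presynaptic genes and 28 of 39 voltage-gated channel genes were higher in the libraries labelled cKO. Axon guidance genes were higher in 29 of 51, cytoskeleton and neurite growth genes in 28 of 45, axon regeneration-associated genes in 20 of 44 and neurogenesis genes in 6 of 19. Growth factors were higher in 24 of 48, with Penk, the proenkephalin gene, at 14.1 ± 5.15 and 4.34 ± 4.64. Among glial and vascular markers, 7 of 17 oligodendrocyte precursor, 7 of 18 microglia and macrophage, 15 of 24 endothelial and 10 of 25 pericyte, smooth muscle and fibroblast markers were higher. Inflammatory cytokines and chemokines were higher in 10 of 19, with the interferon-induced chemokine gene Cxcl10 at 4.66 ± 1.67 and 0.843 ± 0.759. MHC class I and complement genes were higher in 9 of 23, with H2-Q4 at 13.8 ± 8.63 and 2.54 ± 2.73, a gene with close paralogs. Higher members numbered 16 of 35 for apoptosis and p53 targets, 12 of 28 for AP-1, STAT3 and NF-kB genes, 15 of 29 for Nrf2 genes and 23 of 38 for hypoxia and glycolysis genes. They numbered 14 of 31 for cholesterol genes, 19 of 38 for phospholipase A2 and eicosanoid genes, 20 of 40 for lysosome and autophagy genes and 44 of 77 for nuclear-encoded oxidative phosphorylation genes. Chromatin regulators were higher in 22 of 61, histone genes in 19 of 54, cell cycle genes in 17 of 41 and extracellular matrix genes in 29 of 45. In 2 lists, the pericyte, smooth muscle and fibroblast markers and the lysosome genes, the median, mean and test differed in sign. Presynaptic genes, at a mean log2 fold change of 0.12 in the main test, were called higher with edgeR (0.32), DESeq2 (0.30) and array weights (0.38). So were glutamatergic markers, at 0.06, with DESeq2 (0.33) and array weights (0.41), and channel genes with DESeq2 (0.22) and array weights (0.30). Each was also called higher without control replicate 2 and without cKO replicate 1. Without 1 library the means ran from -0.28 to 0.68 for presynaptic genes, -0.42 to 0.73 for glutamatergic markers and -0.20 to 0.60 for channel genes. Without cKO replicate 3 glutamatergic markers were called lower (-0.42), as were GABAergic markers (-0.72, range -0.72 to 0.22). Pericyte, smooth muscle and fibroblast markers, at -0.03, were called higher without control replicate 1 (0.72) and without cKO replicate 2 (0.99, range without 1 library -0.60 to 0.99). Extracellular matrix genes behaved likewise (0.67 and 0.78, range -0.35 to 0.78). Array weights also called both lists higher (0.49 and 0.34), as did leaving out both libraries numbered 2 (0.55 and 0.30).

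Over all 14796 tested genes, limma called 0 higher and 0 lower at an adjusted p under 0.05, the smallest adjusted p being 0.9996. At an unadjusted p under 0.05, 50 genes were higher and 76 lower in the libraries labelled cKO, against 370 per direction by chance alone. On recovered reads edgeR called 0 genes, with 41 higher and 32 lower unadjusted, and DESeq2 called 1, Ifit3, with 97 higher and 78 lower unadjusted. The groups did not overlap in 362 higher and 334 lower genes, 4.70% of those tested where chance gives 10%. Without control replicates 1, 2 and 3 in turn the unadjusted counts were 128, 22 and 18 higher and 66, 43 and 18 lower, and without cKO replicates 1, 2 and 3 they were 432, 14 and 66 higher and 535, 39 and 125 lower. Pearson's r between libraries, taken across genes, which are not independent replicates, was 0.800 to 0.971 between groups, 0.859 to 0.933 within the labelled control and 0.792 to 0.889 within the labelled cKO group.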

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

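Leaving out both libraries numbered 2 was chosen after the data were seen, and the other settings were planned. No gene passed the adjusted threshold in either direction under any alternative except DESeq2 on recovered reads, which called 1 lower gene, Ifit3 (adjusted p 0.0121, against 0.619 to 1.00 for that gene under the others). Genes higher at an unadjusted p under 0.05 numbered 50 in the main test, 95 with no filter, 24 with the stricter filter, 112 with array weights, 97 with DESeq2, 26 without both libraries numbered 2, and 14 to 432 when 1 library was left out. Lower genes numbered 76, and 133, 47, 186, 78, 35 and 18 to 535 in the same order, and 32 with edgeR. Called lists numbered 10, and 5 with no filter, 22 with array weights, 3 to 19 without 1 library, and 0 with the estimated correlation, with fry directional and with fry mixed. Fewer or more genes tested enter the filter counts; the cause of the other moves was not tested.

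Same-numbered libraries deviated together with r of 0.491, 0.301 and 0.0338, the last below the 0.1 set for pairing, so the numbers were not taken as pairs, although each library correlated best with the one of its own number. With a replicate block, 110 genes were higher and 197 lower at an unadjusted p under 0.05, 0 passed the adjusted threshold and 9 lists were called, the ependymal call being lost.

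The Padi4 log2 difference was 1.54 with a pseudocount of 0.1 and 0.075 with 5, as the scale dictates for so low a gene, and 0.19 to 0.49 without 1 library. Quantile normalization, edgeR and DESeq2 gave it no value because it was not among the tested genes, and the filters and robust eBayes do not enter it. Robust eBayes does not enter camera either.

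The interferon-stimulated list had a mean log2 fold change of -0.99, with means from -1.41 to -0.63 over 20 alternatives. It kept its direction and call in 17 of the 20, all with camera at the preset correlation of 0.01. Its estimated correlation was 0.198. The call was lost in the 3 tests without that preset, named in the report, so the 17 do not test the preset. In the other 9 called lists at least 1 left-out library ended the call. Of the 27 lists not called, 19 gained a call with the sign of the test kept under at least 1 alternative, 13 with array weights, 10 without control replicate 2, 8 without both libraries numbered 2, 7 without cKO replicate 2, 6 without cKO replicate 1, 3 with DESeq2, 2 each without control replicate 1 and cKO replicate 3, and 1 with edgeR.

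The sign of the list test changed in 85 fits of 29 lists. In 10 of them, all without 1 library, the list was called in the main test or in that fit, the cause not being tested. Without cKO replicate 3 the mean was -0.42 for glutamatergic markers (range without 1 library -0.42 to 0.73), -0.20 for pan-neuronal (-0.20 to 0.83), -0.066 for oligodendrocyte markers, a mean still below 0 (-0.80 to -0.066), and -0.090 for postsynaptic genes (-0.090 to 0.63). Postsynaptic genes also reversed without control replicate 1 (-0.03) and cKO replicate 2 (-0.02). Ribosomal protein genes reversed without cKO replicate 2 (0.22) and, by the test, control replicate 3 (-0.01; range -0.55 to 0.22). Without cKO replicate 2 histone genes were at 0.41 (-0.63 to 0.41) and cell cycle genes at 0.48 (-0.87 to 0.48). Of 739 list fits, 52 gained and 70 lost a call with the sign kept, and 607 had the call status of the main test, some of these with the sign changed and no call. Of 2925 fits of named genes, 30 changed sign, none called.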

Other observations

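The splits of the libraries for list calls and for the interferon list were planned before their results were seen, and the other tests here were chosen after. The microglia test was run first on all tested markers, then on those well above the floor, and last without Spp1 and Apoe and judged by a 95% interval in place of 2 SE, and only both of these changes together left it open.

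Transcripts of matrix-producing cells varied widely between the libraries of both groups. Fn1 ran from 15.9 to 1944, Col1a1 from 3.54 to 1205 and Col3a1 from 1.82 to 1100 over the 6 libraries, with the high values in control replicate 1, cKO replicate 1 and cKO replicate 3. Spp1 ran from 13.2 to 949.6 over the 6 libraries. Oligodendrocyte precursor genes were more even, with Pdgfra between 362 and 693 and Cspg4 between 106 and 157. Xist reached at most 0.864 and Ddx3y, on the Y chromosome, between 96.4 and 161 in the 6 libraries, all labelled male.

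The 10 ways of parting 6 libraries 3 against 3 are too few for a share under 0.05. For genes past the adjusted threshold the real value was 0, which 10 of the 10 splits reach by necessity, and the highest other 11. For genes at an unadjusted p under 0.05 the real value was 126 and the highest other 2651, with 9 of the 10 giving as many. For called lists the real value was 10 and the highest other 22, with 9 of the 10 giving as many. The split of control replicate 1, cKO replicate 1 and cKO replicate 3 against the rest called 11 genes, Bgn, Col18a1, Col4a1, Col5a2, Col6a3, Cyp1b1, Fn1, Fstl1, Hspg2, Lox and Serpinh1. This and the split with 2651 genes point to a structure of the samples other than the labels.

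Interferon-stimulated genes were lower in the libraries labelled cKO. The low detection in cKO replicate 2 was tested by leaving it out, and the median log2 difference was still -0.62, with 30 of 34 members lower, which argues against that library as the whole cause. Fewer microglia and macrophages in the libraries labelled cKO, cells the CD45 gate would remove, stay open. Spp1 and Apoe were left out because other cells make them too. The remaining 7 such markers with a mean of at least 5 differed by -0.35 (SE 0.31). This was 0.64 above the interferon list, with a 95% interval of -0.20 to 1.48, while the gap was 0.81 (SE 0.14) with both genes. Single log2 fold changes of Ctss, Csf1r, Cd68, P2ry12 and Cx3cr1 were -1.37, -0.72, -0.67, -0.06 and -0.02. Ctss had a mean under 5 over all libraries, so it was not among the 7. The absolute mean difference of the list was 0.99 in the real split and 0.86 in the highest other. So 1 of 10 splits was as large, too few splits for a share under 0.05. Camera at the preset correlation gave the list an unadjusted p of 5.57e-17 in the real split and of 2.54e-05 to 0.996 in the others, so small values also arose without the labels. An effect of the genotype stays open as an untested hypothesis, as do differences in infarct or tissue between animals. Padi4 itself did not bear out the labels.

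Padi4 reads stood in 2 libraries labelled cKO and in none labelled control. Neutrophils, which express Padi4 and which the CD45 gate would remove, are a candidate source. In cKO replicate 2 there were 0 reads of S100a8 and S100a9, abundant neutrophil transcripts, beside 3 of Padi4, which is at the floor. The neutrophil list summed to 19.2 there, 15.7 of it from Lcn2, also an astrocyte marker, against 2.13 to 23.6 in the libraries labelled control. So few reads cannot decide on neutrophil RNA in that library. Csf3r, another neutrophil gene that other myeloid cells express too, had 3 reads in cKO replicate 2 and 14 in cKO replicate 3, but also 13 in cKO replicate 1, which had 0 of Padi4, and 0, 0 and 4 in control replicates 1 to 3. In cKO replicate 3 there were 45 reads of S100a8 and S100a9 beside 12 of Padi4, while control replicate 3 had 56 beside 0, so this source cannot be told apart there. The position of the 15 reads within the gene is not given in the sources used here, so reads from exons outside the deleted part cannot be told apart from intact transcript, and exchanged group labels also stay open, since 0 libraries labelled control had Padi4 above 3 reads and Padi4 may be near that floor in sorted neurons.

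Oligodendrocyte markers summed above pan-neuronal ones although the gate excluded O4-positive cells. Unsorted cells of every type carried over alike would bring microglial genes too. The median of 30 microglia and macrophage markers, 18 of which passed the filter, was 1.64. It was 551 for the 24 oligodendrocyte markers and 22.8 for the median tested gene. Medians of other marker lists were 7.88 for endothelium, 52.4 for astrocytes and 94.7 for pericytes, smooth muscle and fibroblasts. The low microglial values cannot exclude a carry-over of other cells, since the CD45 gate would remove microglia. Another fixed list also holds 3 of the 24 oligodendrocyte and 7 of the 30 microglia markers. Whole oligodendrocytes, their fragments and free RNA were not separated and stay open, and no biological explanation was tested.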
